A study of Homo sapiens with 30 samples.

How the data were processed

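Spatial transcriptomes were measured with Visium, a slide carrying an array of barcoded spots that captures RNA-derived probes in place, on formalin-fixed paraffin-embedded sections. The 30 human specimens were 10 primary pancreatic tumours, 3 normal pancreases, 12 hepatic metastases and 5 lymph nodes, 1 file set per specimen. Per the series description the metastases were matched to the primary tumours and the sections include adjacent normal liver and lymph node. The labels do not tie specimens to patients, so every p-value over specimens treats them as independent, and no patient could be used as a block. Replicate numbers follow the order of deposition within a group.

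The authors ran Space Ranger on GRCh38, per the labels, without stating versions. The deposited gene tables hold UMI counts per gene (unique molecular identifiers, which mark single captured molecules) summed over all spots under tissue, and the number of spots in which each gene was detected. Per the file headers the tables also hold a score per gene, Moran's I, computed by the authors over the spots under tissue. Moran's I measures how much neighbouring spots resemble each other, with 0 for no spatial pattern and higher values for larger domains. The deposited p-values and adjusted p-values belong to that score and were used only to count spatially patterned genes per specimen. The deposited normalized mean signal per spot is scaled within each specimen and was not used for comparisons between specimens. Other deposited columns hold the position of each spot on the array and whether it lies under tissue. Counts per spot and gene were not analysed here, so no spot was clustered and no cell type was assigned to any place in a section.

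Totals per specimen ran from 1244623 to 76609691 UMIs and mean UMIs per spot from 350.1 to 25571. These depths set the precision of every value below. Counting error alone is covered by the counts. The spread between specimens is covered by the tests. The files listed 17924 genes in any specimen and 13713 in every specimen. A gene not listed in a file was counted as 0 there, since the lowest listed count was 1. Of these genes, 18 were left out of every test and plot for privacy, with at most 0.361% of a specimen's counts. The remaining 17906 symbols were looked up in the GRCh38 annotation, in which 17368 matched once and gave the positions used here. Of 396 genes in the gene lists, 21 were listed in no file and could not be tested. Among them were KRT19 and KRT17, which had been chosen for naming, and CEACAM6, LDHA, TPI1, ALDOA, KRT6A, KRT6C, MYH11, FLT1, PRSS2 and CELA3B.

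Gene counts of each specimen were tested with edgeR 4.0.16 in R 4.3.3. Genes passing filterByExpr by group (16810) were scaled by TMM, and a robust quasi-likelihood model was fitted to all 4 groups at once. The 4 comparisons were primary tumour against normal pancreas, hepatic metastasis against primary tumour, lymph node against primary tumour and hepatic metastasis against lymph node. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1, two-sided. Levels are CPM, edgeR's counts scaled to a common library size, on TMM-scaled library sizes, so a specimen's values need not add up to the same total. The standard error of a log2 fold change was its size divided by the square root of the F statistic.

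The 29 gene lists were fixed before the data were examined, as were the tests, the rule for naming genes and most alternative settings. They cover acinar, islet and ductal cells, pancreatic cancer epithelium and its classical and basal-like subtypes, collagen and matrix, myofibroblastic and inflammatory fibroblasts, smooth muscle, endothelium, liver sinusoid, hepatocytes, macrophages, SPP1-type macrophages, neutrophils, T and NK cells, T cell checkpoint and regulatory genes, B cells, plasma cells, lymph node stroma, MHC class II presentation, interferon response, proliferation, hypoxia and glycolysis, mesenchymal transition, Schwann cells, adipocytes, and immediate early and heat shock genes. Each was tested per comparison with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with the correlation estimated per list. The fry test was run beside it. A list score is the mean log2 CPM of its members in a specimen. Named genes were, per comparison, the 8 called genes with the largest positive and the 8 with the largest negative log2 fold change among those with a mean of at least 100 CPM in the higher group, up to 4 list members with the smallest adjusted p, and 19 genes chosen in advance.

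Moran's I was compared between groups with limma (robust, with trend) on the 2134 genes with at least 100 counts in every specimen. Median Moran's I over a list was compared by permutation, exact where a group had fewer than 10 specimens and otherwise with 100000 resamples, with Benjamini-Hochberg adjustment over 87 tests. Spots and UMIs per spot were compared the same way over 8 tests. Correlations between the classical and basal-like scores were computed within primary tumours and within hepatic metastases, a family of 2, with permutation p-values. Permutations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. All tests were two-sided.

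Alternatives covered DESeq2 1.42.0, library totals without TMM, upper quartile factors, no filter on low counts, only genes listed in every specimen, only the 2 groups compared, removal of acinar, islet and hepatocyte genes before scaling, limma voom with sample weights, and no fold minimum. Covariates were UMIs per spot and the hepatocyte or B cell list score. Each specimen was left out in turn. For Moran's I they covered a loess residual on gene count (span 0.3), minimums of 500 and 20 counts, and the number of spots as a covariate. Removal of the 3 specimens of another file layout, of 3 with atypical tissue content and of 3 under 1000 UMIs per spot was added after seeing the data, as were UMIs per spot for Moran's I and left-out specimens for its list medians. Those of atypical content were hepatic metastasis replicates 2 and 8 and lymph node replicate 4. Each count of changed genes was compared with 100 splits of the same specimens, the real one included. Genes changed at both metastatic sites were compared with 20 simulated data sets of unchanged groups and with the primary tumours split into 5 and 5.

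The tests were tried on simulated counts with 200 changed genes among 16810, called at the adjusted p alone. Simulated means of all groups were those of primary tumours. The composition of normal pancreas, where few genes take a large share of counts, was therefore not covered. For primary tumour against normal pancreas the test found 12% of 2-fold and 60% of 4-fold changes, with 5 false calls. For hepatic metastasis against primary tumour these were 49% and 87%, with 6 false calls. For lymph node against primary tumour they were 30% and 79%, with 7 false calls, and for hepatic metastasis against lymph node 22% and 74%, with 4 false calls. Among 2134 genes with simulated Moran's I, shifts of 0.1 were found for 68% of changed genes in the first, 86% in the second and 84% in the third of these comparisons, with 4, 9 and 2 false calls. Each gene was drawn independently, with the same spread in all groups. Effects of depth or section that move many genes of a specimen together were absent, so false calls from them were not measured.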

Results

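Whole sections of 30 specimens of pancreatic cancer and normal pancreas were profiled by probe-based spatial transcriptomics. The files held 97020 spots under tissue, where the series text states 91496. Spots per specimen averaged 3651 ± 508.5 (SD, n = 10) in primary tumours, 3306 ± 525.4 (n = 3) in normal pancreas, 2730 ± 1001 (n = 12) in hepatic metastases and 3568 ± 398.1 (n = 5) in lymph nodes. Total UMIs ran from 5210951 to 36481216 in primary tumours and from 15966348 to 76609691 in normal pancreas. They ran from 1244623 to 23878123 in hepatic metastases and from 13769399 to 39730628 in lymph nodes. Hepatic metastases had fewer spots than primary tumours (permutation p = 0.0123, adjusted p = 0.0396). UMIs per spot on the log2 scale were lower in primary tumours (11.62 ± 0.755) than in normal pancreas (13.72 ± 1.19; exact permutation p = 0.014, adjusted p = 0.0396). They were also lower in hepatic metastases (10.88 ± 1.39) than in lymph nodes (12.57 ± 0.565; exact permutation p = 0.0149, adjusted p = 0.0396). Lymph nodes against primary tumours gave an exact permutation p of 0.0333, adjusted p = 0.0666. The 20 most abundant genes took 47.5% to 75.2% of counts in normal pancreas and 6.17% to 24.1% in the other specimens. Between specimens of a group, the correlation of log2 CPM across genes, which are not independent replicates, ran from 0.805 in hepatic metastases to 0.980 in normal pancreas. Below, the values after ± beside log2 fold changes are standard errors and those beside levels are SDs.

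The comparison of primary tumour with normal pancreas asks how the tissue of the tumour differs from the organ in which it grows. Genes of acinar cells, the exocrine cells that secrete digestive enzymes, were far lower in the 10 primary tumours than in the 3 normal pancreases, with a median log2 fold change of -11.88. Collagen and matrix genes were higher, with a median of 5.49. Genes of cancer epithelium, macrophages and antigen presentation by MHC class II rose as well, though no list passed camera with an estimated correlation (adjusted p = 0.0613 or more). Of 16810 genes tested, 4517 were called, 2631 of them higher in primary tumours and 1886 lower.

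All 19 measured acinar genes fell, and all 19 also when adjusted over the list alone (camera adjusted p = 6.6e-28, adjusted p = 0.0613 with an estimated correlation). PNLIP, pancreatic lipase (ENSG00000175535, GRCh38 chromosome 10, 116545931 to 116567855), went from 309300 ± 196000 CPM in normal pancreas to 13.5 ± 16.1 CPM in tumours, a log2 fold change of -14.48 ± 1.62 (adjusted p = 7.52e-08). Its cofactor CLPS changed by -14.40 ± 1.66, the trypsinogen PRSS1 by -13.08 ± 1.53, the chymotrypsin CTRC by -12.36 ± 1.39 and the acinar transcription factor RBPJL by -12.53 ± 1.13. SYCN (-14.07), the elastase CELA2B (-13.86) and the phospholipase PLA2G1B (-12.94) were the others among the 8 largest falls of abundant genes. PRSS1 and other digestive enzyme genes have near-identical copies, so the share of each copy is uncertain. Of 13 ductal genes, KRT7, a keratin, rose (4.56 ± 1.15), while SLC4A4 (-5.47 ± 0.68) and CFTR (-3.48 ± 0.87), both ion transporters of duct cells, fell, and without TMM CFTR was not called, at -1.93. Over the list 1 gene rose, 3 fell and 9 did not pass, among them EPCAM at -0.19 ± 0.76 (camera adjusted p = 0.587). Islet genes, which encode hormones and their processing, had 1 fall among 16, 2 without primary tumour replicates 2 or 10 (camera adjusted p = 0.0504), with INS at -2.39 ± 1.34 and not called.

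All 20 collagen and matrix genes rose, and all 20 adjusted over the list alone (camera adjusted p = 8.47e-22, adjusted p = 0.0613 with an estimated correlation). COL1A1, a chain of the main fibrillar collagen, went from 72.4 ± 39.7 to 8578 ± 3886 CPM, a log2 fold change of 6.89 ± 1.02. FN1, fibronectin, rose by 7.15 ± 0.82, COL3A1 by 5.90 ± 0.82 and COL10A1 by 8.36 ± 1.51. Of 14 genes of myofibroblastic fibroblasts, 13 rose over all genes and over the list alone (adjusted p = 0.0731 with an estimated correlation), including POSTN (8.16 ± 1.26) and the activin subunit INHBA (7.13 ± 0.81). Of 12 mesenchymal transition genes 10 rose, 11 adjusted over the list alone (adjusted p = 0.0613 with an estimated correlation). Inflammatory fibroblast genes went both ways, with 2 of 14 higher and 1 lower. The complement gene C3 was higher at 3.11 ± 0.93, not called without normal pancreas replicate 2, at 2.72. The chemokine CXCL12 was lower at -2.10 ± 0.71, not called without normal pancreas replicate 1 (-2.07) or 2 (-1.69) or without TMM (-0.64). In this list 1 gene was higher and 0 lower without normal pancreas replicate 1, and 0 were called by edgeR without normal pancreas replicate 2.

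Of 17 pancreatic cancer epithelium genes 15 rose, 15 adjusted over the list alone (camera adjusted p = 1.54e-07, adjusted p = 0.193 with an estimated correlation). They included S100A6, a calcium-binding protein (4.70 ± 0.89), and the surface antigen CEACAM5 (8.58 ± 2.53), while the mucin MUC5AC was not called at 1.20 ± 1.63. The call of CEACAM5 was lost without normal pancreas replicate 1, at 8.08, and with limma voom, at 7.62, and MUC5AC was called without normal pancreas replicate 2, at 8.04. Basal-like subtype genes had 13 of 20 higher, 18 adjusted over the list alone, with TNS4 at 7.44 ± 1.78 (adjusted p = 0.18 with an estimated correlation). Classical subtype genes had 8 of 23 higher, 10 adjusted over the list alone (adjusted p = 0.622 with an estimated correlation), and GATA6, a transcription factor of that subtype, was not called at -0.84 ± 0.46. GATA6 was called lower without primary tumour replicate 6, at -1.24, and with limma voom, at -1.20. Proliferation genes had 11 of 15 higher, 13 adjusted over the list alone, with MKI67 at 4.30 ± 1.01 (adjusted p = 0.323 with an estimated correlation). Leaving out normal pancreas replicate 1 left 8 cancer epithelium, 1 classical and 7 proliferation genes. Leaving out normal pancreas replicate 2 left 7 basal-like and 5 classical genes, and replicate 3 left 5 classical genes, while DESeq2 called 15.

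All 14 macrophage genes rose, with CD68 at 3.67 ± 0.62 and the complement gene C1QC at 3.15 ± 0.53 (14 adjusted over the list alone, adjusted p = 0.0747 with an estimated correlation). Of 10 genes of SPP1-type macrophages 8 rose, 8 adjusted over the list alone, among them MMP9 (6.55 ± 1.29) and TREM2 (3.69 ± 0.82), while SPP1 itself was not called at 1.41 ± 1.20, but passed without TMM, at 3.33 (adjusted p = 0.0747 with an estimated correlation). All 10 MHC class II genes rose, including their master regulator CIITA at 2.72 ± 0.55 (10 adjusted over the list alone, adjusted p = 0.18 with an estimated correlation). Interferon response genes had 12 of 13 higher, 12 adjusted over the list alone, with IFI27 at 4.28 ± 0.91 (adjusted p = 0.232 with an estimated correlation). T and NK cell genes had 9 of 15 higher, 12 adjusted over the list alone, with CD3E at 3.02 ± 0.92 (adjusted p = 0.389 with an estimated correlation). Leaving out normal pancreas replicate 1, 2 or 3 ended the call of CD3E, at 3.04, 3.08 and 2.92, and left 3, 2 and 3 genes of its list. With UMIs per spot as a covariate 2 of the list were called and CD3E was not, at 1.65. T cell checkpoint and regulatory genes had 9 of 11 higher, 10 adjusted over the list alone, with FOXP3 at 3.34 ± 0.77 (adjusted p = 0.158 with an estimated correlation). Neutrophil genes had 6 of 9 higher, 6 adjusted over the list alone (adjusted p = 0.174 with an estimated correlation). Without normal pancreas replicate 2 the SPP1-type macrophage list had 4 genes higher, and without normal pancreas replicate 1 the interferon response list had 7.

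The largest rises of abundant genes were immunoglobulin constant genes, IGHG3 at 11.72 ± 2.60, IGHG1 at 9.08 ± 2.37 and IGHG2 at 8.90 ± 2.55, whose near-identical sequences leave the share of each uncertain. IGHG4 had 3 counts over the 3 normal pancreases and is given without a fold. The joining segment IGHJ6 rose by 9.09 ± 2.51. With limma voom the calls of IGHG2 (6.90) and IGHJ6 (6.74) were lost. The plasma cell list went both ways, with 5 of 10 higher, such as SDC1 (2.97 ± 0.50), and 3 lower, among them XBP1 (-3.23 ± 0.35) and FKBP11 (-3.13 ± 0.23), genes of secretory cells in general (camera adjusted p = 0.518). The cystatin CST1 rose by 10.01 ± 3.30, a call lost without normal pancreas replicate 1, 2 or 3, at 9.60, 9.85 and 10.90, with limma voom (7.43) and with UMIs per spot as a covariate (9.42). Immediate early and heat shock genes had 5 of 12 lower and a median of -1.05, which turned to 0.73 without TMM (camera adjusted p = 0.0756). The heat shock gene HSPA1A was lower at -3.02 ± 0.78, with its call lost without normal pancreas replicate 2, at -1.99, without TMM, at -1.76, and with limma voom, at -1.93. Of its list 1 gene was lower and 1 higher without normal pancreas replicate 1, and 0 were called by edgeR without normal pancreas replicate 2. Library totals without TMM called 10902 genes, 96.3% of them higher against 58.2% with TMM, and moved the median of all genes from -0.019 to 1.57. No list passed camera with an estimated correlation, and the normal group had 3 specimens.

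**Figure D1:**
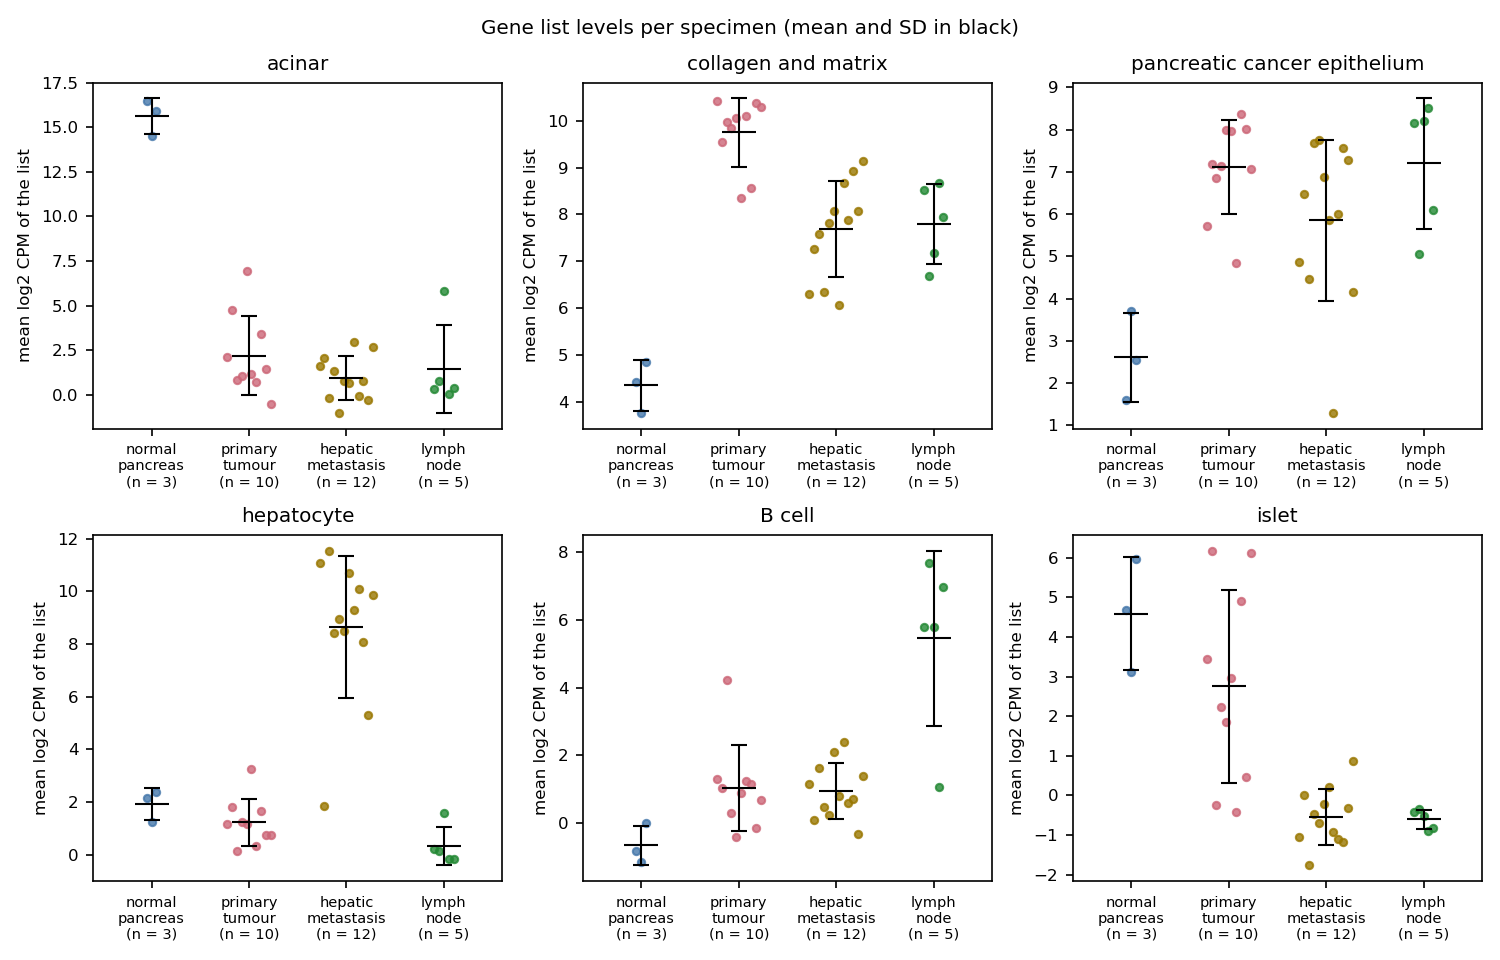
Mean log2 CPM of 6 gene lists (vertical axes) in each specimen (points) by group (horizontal axes), with the group mean and SD in black. The acinar list averaged 15.64 in normal pancreas and 2.20 in primary tumours, the hepatocyte list 8.64 in hepatic metastases against 1.22 in primary tumours, and the B cell list 5.45 in lymph nodes against 1.03.

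The comparison of hepatic metastasis with primary tumour asks how tumour tissue in the liver differs from that in the pancreas. Genes of hepatocytes, the main cells of the liver, were higher in the 12 hepatic metastases, with a median log2 fold change of 8.78. Genes of the liver sinusoids were higher too, with a median of 4.59. Collagen and matrix genes were lower, with a median of -1.70, and so were those of myofibroblastic fibroblasts (-1.74) and islets (-4.79). Of these lists the hepatocyte genes alone passed camera with an estimated correlation (adjusted p = 0.0438, the others 0.175 or more). Of 16810 genes, 1659 were called, 921 higher in hepatic metastases and 738 lower.

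Of 21 hepatocyte genes 20 rose, 20 adjusted over the list alone, the single list here that passed camera with an estimated correlation as well (adjusted p = 0.0438). ALB, albumin (ENSG00000163631, chromosome 4, 73404287 to 73421482), went from 12.6 ± 20.8 CPM in primary tumours to 24010 ± 39940 CPM, a log2 fold change of 10.90 ± 1.32 (adjusted p = 5.58e-07). The apolipoproteins APOA1 (10.70 ± 1.20), APOC3 (10.45 ± 1.13) and APOA2 (10.38 ± 1.08) and the plasma proteins AHSG (10.10 ± 1.09), HP (10.06 ± 0.97) and HRG (10.42 ± 1.05) rose with it. So did AGXT, a liver enzyme of glyoxylate metabolism (10.69 ± 1.22). The hepatocyte score ran from 1.86 in hepatic metastasis replicate 2, inside the range of primary tumours (0.12 to 3.24), to 11.54. Of 8 liver sinusoid genes 7 rose, 7 adjusted over the list alone, including the ficolins FCN2 (6.19 ± 0.84) and FCN3 (4.72 ± 0.64), secreted lectins of innate immunity (adjusted p = 0.175 with an estimated correlation).

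Of 20 collagen and matrix genes 17 fell, 18 adjusted over the list alone (camera adjusted p = 2.49e-14, adjusted p = 0.175 with an estimated correlation). COL12A1 fell by 3.14 ± 0.41, COL11A1 by 3.49 ± 0.62 and COL1A1 by 2.43 ± 0.44, from 8578 ± 3886 to 1596 ± 956.4 CPM. FN1 was not called at -0.82 ± 0.34. Of 14 myofibroblastic genes 11 fell, 12 adjusted over the list alone, with POSTN at -2.02 ± 0.51 and INHBA at -1.79 ± 0.34 (adjusted p = 0.175 with an estimated correlation). SFRP2, a secreted modulator of Wnt signalling (-4.79 ± 0.76), and APOD (-5.33 ± 0.68), outside the lists, were among the 8 largest falls of abundant genes. Of 6 smooth muscle genes 5 fell, 5 adjusted over the list alone, with DES, desmin (-5.69 ± 1.14), and ACTG2 (-3.49 ± 0.65) as examples (adjusted p = 0.412 with an estimated correlation). Without hepatic metastasis replicates 1, 2, 4, 5, 7, 9 or 11 or primary tumour replicates 3, 7 or 9, and with limma voom, 3 were called, and DES was not called with limma voom, at -2.81. The hepatocyte score was 8.64 ± 2.70 in these metastases against 1.22 ± 0.88 in primary tumours.

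Of 16 islet genes 15 fell, 15 adjusted over the list alone, with the hormones GCG (-8.97 ± 1.26), INS (-8.85 ± 1.33) and SST (-6.84 ± 1.02) as examples (adjusted p = 0.203 with an estimated correlation). With limma voom GCG (-5.98) and INS (-6.37) were not called. Acinar genes had 10 of 19 lower, 13 adjusted over the list alone, with the chymotrypsinogens CTRB1 (-6.96 ± 1.51) and CTRB2 (-5.58 ± 1.45) as examples (camera adjusted p = 0.0371, adjusted p = 0.959 with an estimated correlation). This fall rested on 1 specimen, since 1 of the 19 was called without primary tumour replicate 5, where CTRB2 was at -3.30 and not called. With limma voom 0 were called, with CTRB1 at -1.34 and CTRB2 at -1.66, and with UMIs per spot as a covariate 4. LIPF, gastric lipase, was lower at -6.50 ± 1.60, a direction that turned without primary tumour replicate 7, to 2.87, and with DESeq2, to 1.08, and with limma voom it was at -0.36 and not called.

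Lists of immune cells showed little change between these groups. No gene of the macrophage (14), T and NK cell (15), neutrophil (9), MHC class II (10), interferon response (13) or plasma cell (10) list was called by edgeR, over all genes or over the list alone. CD68 lay at 156 ± 141 against 160 ± 48.5 CPM, a log2 fold change of -0.04 ± 0.31, and CD3E at 0.24 ± 0.49. MKI67 of the proliferation list, in which no gene of 15 was called, was at -0.37 ± 0.49. Leaving out single specimens gave 1 call in the macrophage list (hepatic metastasis replicates 3 or 5, primary tumour replicates 4 or 8), the T and NK cell list (primary tumour replicate 8), the neutrophil and plasma cell lists (hepatic metastasis replicate 8) and the proliferation list (hepatic metastasis replicate 9). In the SPP1-type macrophage list APOE (2.93 ± 0.39) and APOC1 (3.94 ± 0.69), which hepatocytes also express, rose and MMP9 fell (-1.81 ± 0.56), a call lost without primary tumour replicate 7 (-1.57) or the 3 specimens of another file layout (-1.69). Inflammatory fibroblast genes had 4 of 14 higher, 5 adjusted over the list alone, including C3 (1.66 ± 0.51) and the chemokine CXCL2, at 122 ± 132 against 30.5 ± 19.7 CPM, and 1 lower, 3 over the list alone, or 0 to 2 leaving out single specimens (camera adjusted p = 0.57). The call of C3 was lost without hepatic metastasis replicate 1, at 1.39. With the hepatocyte score as a covariate, which nearly follows the groups, the folds of C3 and CXCL2 reversed. The sections include liver, so the rises of these 2 genes cannot be assigned to fibroblasts. CXCL12 was at 1.43 ± 0.53 and not called, but passed without primary tumour replicate 7 (2.17) or without hepatic metastasis replicates 2 (1.52), 5 (1.51), 10 (1.51) or 11 (1.54). It also passed with limma voom (1.96) and DESeq2 (1.495) and without the other file layout (1.65).

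Of 17 pancreatic cancer epithelium genes 1 fell, the tight junction gene CLDN18 (-3.25 ± 0.92), and 1 adjusted over the list alone (camera adjusted p = 0.0209, adjusted p = 0.959 with an estimated correlation). With limma voom CLDN18 was not called, at -2.25, and DESeq2 called 4 of the list. Leaving out hepatic metastasis replicates 5, 6, 10 or 11 or primary tumour replicates 1, 3, 4 or 7 gave 2 or 3. CEACAM5 (-2.04 ± 0.98), EPCAM (-0.49 ± 0.50) and GATA6 (-0.10 ± 0.31) were not called. Hepatic metastasis replicate 8 had the lowest cancer epithelium score of its group, 1.299, under the range of normal pancreas (1.590 to 3.697). It also had the highest macrophage (8.077) and heat shock (10.102) scores of its group, at 715 UMIs per spot. Hypoxia and glycolysis genes had 3 of 13 lower, 3 adjusted over the list alone, with the glycolytic enzyme PGAM1 (-1.18 ± 0.24) and the cytokine MIF (-1.16 ± 0.28), whose call was lost without primary tumour replicate 4 (-0.97), with limma voom (-0.99) and with UMIs per spot as a covariate (-0.97; adjusted p = 0.294 with an estimated correlation). Without primary tumour replicate 4, 1 gene of the list was called. Schwann cell genes had 4 of 8 lower, 4 adjusted over the list alone, with S100B at -2.22 ± 0.49 (camera adjusted p = 0.409), but 1 without primary tumour replicate 10 and 2 with limma voom or UMIs per spot as a covariate. With the hepatocyte score as a covariate 170 genes were called instead of 1659, 26 of them shared, and no hepatocyte, collagen or islet gene among them. The fold of ALB went from 10.90 ± 1.32 to 0.52 ± 0.79, which was set in advance, since ALB is part of that score. The folds of islet and some collagen genes kept much of their size with wider errors (GCG -7.77 ± 2.55, INS -8.29 ± 2.81, SST -7.98 ± 2.21, COL12A1 -2.66 ± 1.10), and INHBA was at -0.58 ± 0.86.

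The comparison of lymph node with primary tumour asks the same of whole sections of lymph nodes, which are organs of resident lymphocytes. All 12 measured B cell genes were higher in the 5 lymph nodes than in the 10 primary tumours, with a median log2 fold change of 4.72. Of the lymph node stroma list 3 of 8 genes were called higher and of the T and NK cell list 5 of 15, with medians of 2.82 and 1.47 (adjusted p = 0.104 and 0.235 with an estimated correlation). Collagen and matrix genes were lower, with a median of -1.72, and islet genes with a median of -6.05 (adjusted p = 0.114 and 0.118 with an estimated correlation). Of 16810 genes, 909 were called, 470 higher in lymph nodes and 439 lower.

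The B cell list had 12 of 12 higher over all genes and over the list alone, and was the single list here that passed camera with an estimated correlation too (adjusted p = 0.0345). MS4A1, the B cell antigen CD20 (ENSG00000156738, chromosome 11, 60455847 to 60470752), went from 4.73 ± 10.9 to 184 ± 173 CPM, a log2 fold change of 5.26 ± 1.02 (adjusted p = 0.00203). The kinase BLK (5.54 ± 0.89), the receptor FCRL1 (5.49 ± 0.92) and CD79A of the B cell receptor (4.50 ± 0.76) were examples, and NIBAN3 (4.99 ± 0.83) and AC119396.1 (4.16 ± 0.71), outside the list, rose likewise. Lymph node replicate 4 stood apart, with a B cell score of 1.08 and a lymph node stroma score of 2.50, inside the ranges of primary tumours (-0.40 to 4.23 and 1.65 to 5.795). Of 8 lymph node stroma genes 3 rose, 7 adjusted over the list alone, including the homing chemokine CCL21 (4.27 ± 0.89) and its receptor CCR7 (4.14 ± 0.79; adjusted p = 0.104 with an estimated correlation). It had 5 without lymph node replicate 4, 6 without primary tumour replicates 3 or 4, 6 with DESeq2 and 7 with limma voom. T and NK cell genes had 5 of 15 higher, 8 adjusted over the list alone, with CD3D at 2.87 ± 0.59 and CD3E at 2.69 ± 0.59 (adjusted p = 0.235 with an estimated correlation). Both calls were lost without lymph node replicate 2, at 2.24 and 2.002, where 0 of the list were called by edgeR, and 3 were called without lymph node replicate 5. UMIs per spot as a covariate gave 9. Among T cell checkpoint and regulatory genes 2 of 11 rose, 2 adjusted over the list alone, with the costimulator ICOS at 2.09 ± 0.54, not called without lymph node replicate 2 (1.72) or 5 (1.90; adjusted p = 0.396 with an estimated correlation). MHC class II genes had 3 of 10 higher, 3 adjusted over the list alone, with HLA-DOB at 2.63 ± 0.42 (adjusted p = 0.396 with an estimated correlation). The plasma cell list had 2 of 10 higher, 3 adjusted over the list alone, with POU2AF1 at 3.03 ± 0.70, not called without lymph node replicate 2, at 2.61 (adjusted p = 0.299 with an estimated correlation). The lectin CLEC4M of the liver sinusoid list, which lymph node sinuses also express, rose by 5.96 ± 1.08, with 2 of that list's 8 genes higher (adjusted p = 0.587 with an estimated correlation). Leaving out lymph node replicate 2 left 0 checkpoint, 0 plasma cell, 1 MHC class II and 1 liver sinusoid gene, and lymph node replicate 5 left 0, 1 and 1 of the first 3. The MHC class II list had 1 without primary tumour replicates 2, 5, 6, 7 or 9, the checkpoint list 1 without primary tumour replicates 1, 2, 4, 5, 6, 9 or 10, and the liver sinusoid list 1 without lymph node replicate 3. With limma voom 4 plasma cell genes were called.

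Of 20 collagen and matrix genes 10 fell, 19 adjusted over the list alone (camera adjusted p = 3.2e-18, adjusted p = 0.114 with an estimated correlation). COL11A1 fell by 3.78 ± 0.90, COL6A1 by 2.04 ± 0.46 and COL12A1 by 2.35 ± 0.55, the last not called without lymph node replicate 2, at -2.13. The list had 2 genes lower without lymph node replicate 2, 4 without lymph node replicates 3 or 5, 5 without primary tumour replicates 1 or 10, 6 without primary tumour replicates 7 or 9, and 17 with DESeq2. COL1A1 (-1.60 ± 0.59) and FN1 (-1.48 ± 0.47) were not called, but COL1A1 passed with DESeq2 (-1.66). FN1 passed with DESeq2 (-1.55), limma voom (-1.94) and UMIs per spot as a covariate (-1.775), without TMM (-1.54), with upper quartile factors (-1.61), with genes listed in every specimen (-1.55) and with 3 lists removed (-1.51). It also passed without primary tumour replicates 6 or 8 (-1.57 in both), lymph node replicates 1 (-1.72) or 4 (-1.94) or 3 specimens of atypical tissue content (-1.935). Myofibroblastic genes had 2 of 14 lower, 7 adjusted over the list alone, with INHBA at -2.09 ± 0.48 and POSTN not called at -0.68 ± 0.65 (adjusted p = 0.188 with an estimated correlation). DESeq2, limma voom and UMIs per spot as a covariate each called 6 of them, and 4 or 5 were called without lymph node replicate 4 or primary tumour replicates 6 or 8. Mesenchymal transition genes had 3 of 12 lower, 4 adjusted over the list alone, among them the gelatinase MMP2 at -3.47 ± 0.78 (adjusted p = 0.135 with an estimated correlation), and 5 without lymph node replicate 1. Outside the lists HAND2, a transcription factor (-4.09 ± 0.71), APOD (-3.74 ± 0.91) and SFRP2 (-3.76 ± 1.05) fell. The call of APOD was lost without lymph node replicate 2 (-3.72), and that of SFRP2 without lymph node replicates 1 (-3.60), 2 (-3.81), 3 (-3.50) or 5 (-3.83).

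Islet genes had 13 of 16 lower, 15 adjusted over the list alone, with GCG at -10.79 ± 2.04, INS at -10.08 ± 2.09 and CHGA at -8.06 ± 1.49 (adjusted p = 0.118 with an estimated correlation). TTR, a carrier of thyroid hormone that islets also express, was at -8.72 ± 2.03. With limma voom 1 of the 16 was called, and GCG (-7.07), INS (-6.45), CHGA (-6.23) and TTR (-5.25) were not. LIPF was at -9.48 ± 2.75, and without primary tumour replicate 7 at 0.14 and not called, as with limma voom, at -1.39. Leaving out lymph node replicate 1, 2, 3, 4 or 5 also ended its call, at -9.54, -9.69, -9.62, -9.30 and -9.25. No gene of the pancreatic cancer epithelium (17), classical (23), basal-like (20), macrophage (14) or proliferation (15) lists was called by edgeR, over all genes or over the list alone. Leaving out single specimens gave 2 macrophage genes lower (lymph node replicate 4), and 1 classical (primary tumour replicates 6 or 8) and 1 proliferation gene higher (lymph node replicate 4 or primary tumour replicate 4). The classical list passed camera upwards (adjusted p = 0.00863, adjusted p = 0.587 with an estimated correlation), with a median of 0.70. EPCAM (0.63 ± 0.62), CEACAM5 (1.64 ± 1.18) and MKI67 (0.64 ± 0.61) were not called. Without lymph node replicate 2 the comparison called 269 genes and without lymph node replicate 5 it called 476, against 909. DESeq2 called 1403, 38.9% of them higher against 51.7%, and the B cell score as a covariate gave 181, 87 of them shared. With it MS4A1 was at -0.44 ± 0.50, which was set in advance, since MS4A1 is part of that score. The folds of COL11A1 (-3.06 ± 0.91), MMP2 (-3.77 ± 0.99), GCG (-9.53 ± 4.17) and INS (-8.90 ± 4.25) kept most of their size without passing. Those of CCL21 and its receptor CCR7, both in the lymph node stroma list, reversed.

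**Figure D2:**
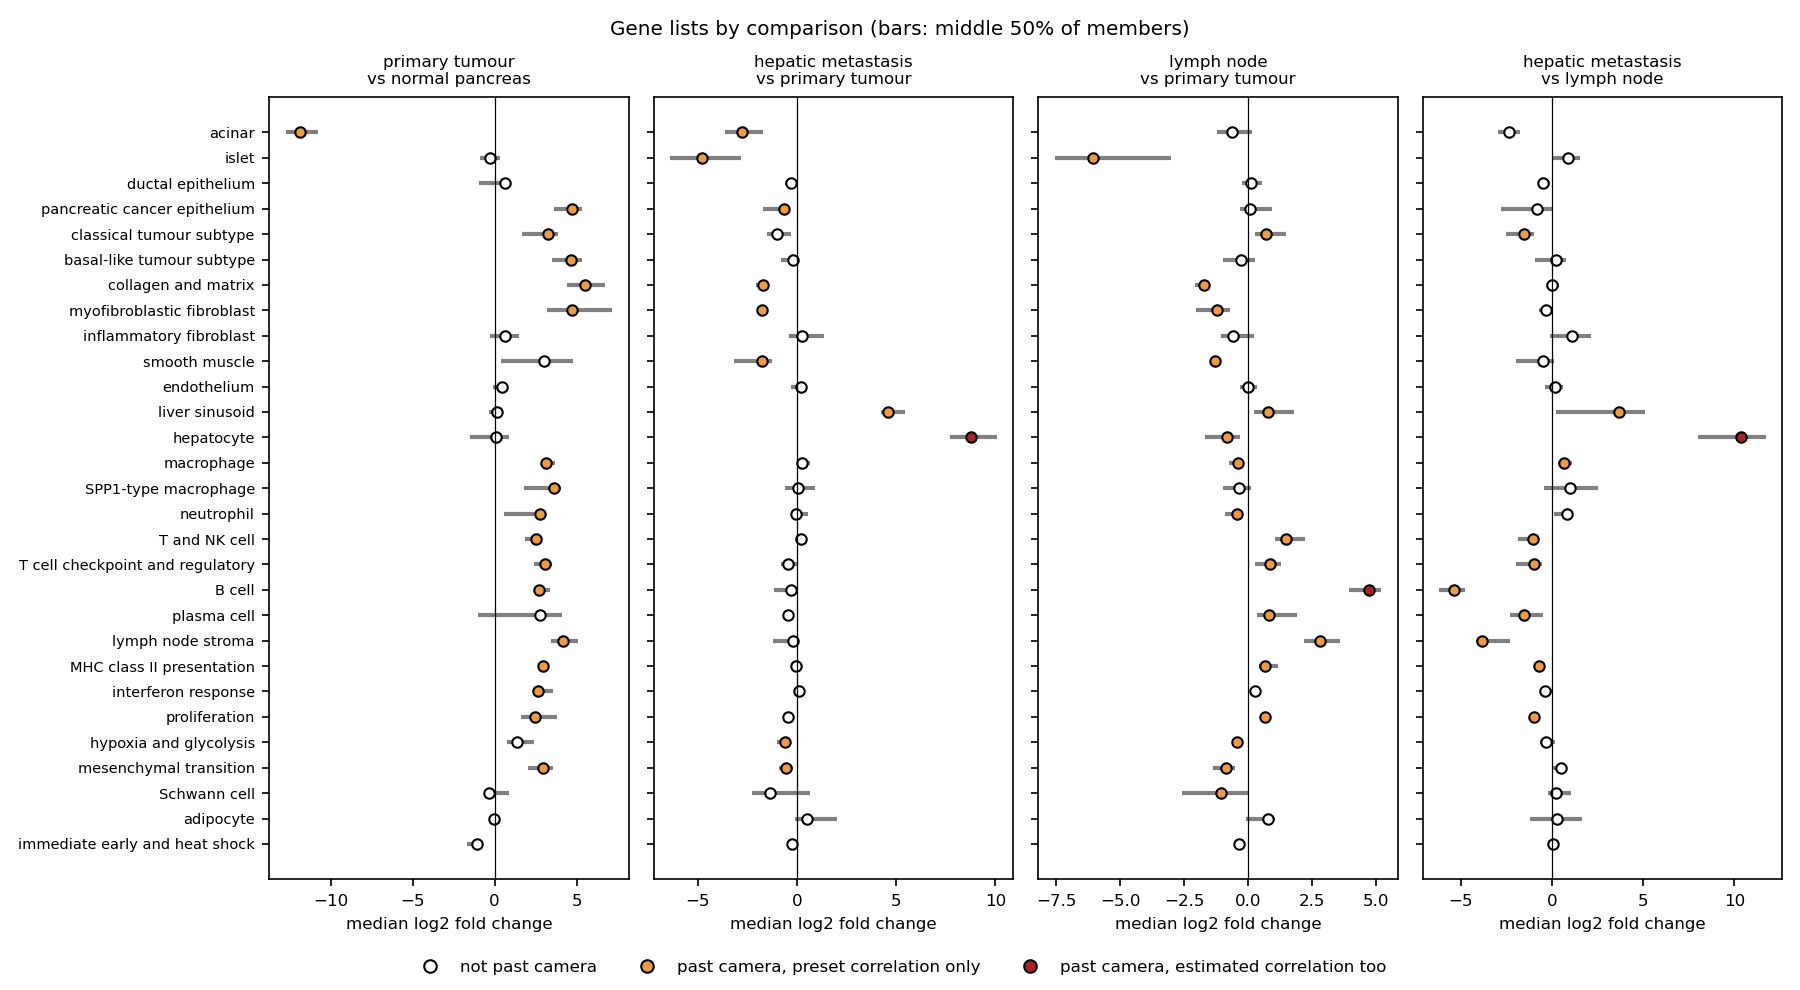
Median log2 fold change of the members of each of the 29 gene lists (horizontal axes, first group over second) in the 4 comparisons, with bars over the middle 50% of members and colours for the camera test. The lists that passed with an estimated correlation were the hepatocyte list, at 8.78 and 10.38 in the hepatic metastasis comparisons, and the B cell list, at 4.72 in lymph nodes against primary tumours.

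The comparison of hepatic metastasis with lymph node sets the 2 metastatic sites side by side. Hepatocyte genes were higher in the 12 hepatic metastases than in the 5 lymph nodes, with a median log2 fold change of 10.38. B cell genes were lower, with a median of -5.38, and so were lymph node stroma genes, at -3.86 (adjusted p = 0.0878 and 0.208 with an estimated correlation). Collagen and matrix genes, lower than in primary tumours at both sites, differed by a median of 0.006 with 0 of 20 called by edgeR, over all genes or over the list alone. Of 16810 genes, 1668 were called, 938 higher in hepatic metastases and 730 lower.

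All 21 hepatocyte genes were higher, 21 adjusted over the list alone, and the list passed camera with an estimated correlation too (adjusted p = 0.0287). The fibrinogen chains FGA (12.85 ± 1.82), FGG (12.38 ± 1.74) and FGB (11.78 ± 1.59), ALB (12.14 ± 1.94) and APOA2 (12.06 ± 1.61) were among the 8 largest. FGA (ENSG00000171560, chromosome 4, 154583126 to 154590742) went from 0.681 ± 0.916 CPM in lymph nodes to 4874 ± 4596 CPM. The acute phase genes ORM1 (13.40 ± 2.27) and CRP (12.34 ± 2.29), outside the list, were the others, with AGXT, which had 2 counts over the 5 lymph nodes and is given without a fold. Liver sinusoid genes had 5 of 8 higher, 5 adjusted over the list alone, with FCN2 at 6.66 ± 1.16 (adjusted p = 0.501 with an estimated correlation). Macrophage genes had 2 of 14 higher, 2 adjusted over the list alone, one of them the receptor CD14 at 1.63 ± 0.47 (adjusted p = 0.678 with an estimated correlation). The call of CD14 was lost without lymph node replicate 1 (1.51) or 2 (1.545), where 0 of the list were called by edgeR, and with UMIs per spot as a covariate (1.59). The list had 4 without lymph node replicate 4, 1 without lymph node replicates 3 or 5 or hepatic metastasis replicates 1, 8, 9, 10 or 12, 5 with DESeq2 and 4 with limma voom. In the SPP1-type macrophage list APOE was higher (2.57 ± 0.51) and MMP9 lower (-2.56 ± 0.64), with 3 of 10 higher, 4 adjusted over the list alone, and 1 lower (camera adjusted p = 0.302). Among inflammatory fibroblast genes C3 (3.16 ± 0.73) and CXCL12 (2.41 ± 0.73) were higher and IL6 was lower (-2.09 ± 0.50), with 3 of 14 higher, 5 adjusted over the list alone (camera adjusted p = 0.207). CXCL12 was not called without lymph node replicate 1 (2.22), 3 (2.355) or 4 (2.22), with UMIs per spot as a covariate (1.54), or without the specimens of atypical tissue content (2.11) or under 1000 UMIs per spot (1.96). With the hepatocyte score as a covariate, which nearly follows the groups, the folds of CD14, APOE and C3 reversed.

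All 12 B cell genes were lower, 12 adjusted over the list alone (camera adjusted p = 2.25e-15, adjusted p = 0.0878 with an estimated correlation). MS4A1 was at -6.60 ± 1.04, FCRL1 at -6.25 ± 0.91, CD79A at -6.17 ± 0.77 and BLK at -5.40 ± 0.85, with NIBAN3 at -4.29 ± 0.77. The lymph node stroma list had 6 of 8 genes lower, 8 adjusted over the list alone (adjusted p = 0.208 with an estimated correlation). In it CCR7 was at -4.33 ± 0.76 and FDCSP, a product of follicular dendritic cells, at -5.04 ± 0.88. T and NK cell genes had 5 of 15 lower, 6 adjusted over the list alone, with CD3D at -2.66 ± 0.57 (adjusted p = 0.566 with an estimated correlation). CD3E was lower at -2.46 ± 0.57, and not called without lymph node replicate 2, at -1.76. That list had 1 gene lower without lymph node replicate 2, 2 without lymph node replicate 5, 8 without hepatic metastasis replicate 8 and 10 with UMIs per spot as a covariate. T cell checkpoint and regulatory genes had 5 of 11 lower, 5 adjusted over the list alone, with CTLA4 at -2.16 ± 0.51 (adjusted p = 0.496 with an estimated correlation). Plasma cell genes had 6 of 10 lower, 6 adjusted over the list alone, with POU2AF1 at -3.65 ± 0.68 (adjusted p = 0.496 with an estimated correlation). Leaving out lymph node replicate 2 left 3 checkpoint and 3 plasma cell genes, and lymph node replicate 3 left 3 plasma cell genes.

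Classical subtype genes had 7 of 23 lower in hepatic metastases, 8 adjusted over the list alone (camera adjusted p = 0.000282, adjusted p = 0.566 with an estimated correlation). The intestinal cadherin CDH17 was lower at -4.19 ± 1.15, the secretory gene AGR2 at -2.81 ± 0.75 and TFF3 at -3.27 ± 0.93. Of 17 pancreatic cancer epithelium genes 5 were lower, 5 adjusted over the list alone, with CEACAM5 at -3.68 ± 1.13 (camera adjusted p = 0.0823), and DMBT1, outside the lists, was at -4.15 ± 1.19. Leaving out lymph node replicate 4 ended the calls of CDH17 (-1.84), DMBT1 (-3.50), CEACAM5 (-2.43) and TFF3 (-2.78). Leaving out lymph node replicate 3 ended those of DMBT1 (-3.49) and CEACAM5 (-3.48), and lymph node replicate 1 that of TFF3 (-2.80). The classical list had 2 genes lower without lymph node replicate 4 and 4 without lymph node replicates 1 or 3 or hepatic metastasis replicates 1, 2, 3, 7, 9 or 12. The cancer epithelium list had 2 without lymph node replicates 3 or 4. With limma voom 0 genes of both lists were called, with AGR2 at -2.14, CDH17 at -3.07, TFF3 at -2.97, CEACAM5 at -3.11 and DMBT1 at -2.51. UMIs per spot as a covariate left 2 and 1 and ended the same 5 calls (AGR2 at -2.62, CDH17 at -4.14, TFF3 at -3.26, CEACAM5 at -3.39 and DMBT1 at -4.05). Of 15 proliferation genes the cyclin CCNA2 was lower (-1.59 ± 0.37), 1 adjusted over the list alone (adjusted p = 0.566 with an estimated correlation), and MKI67 was not called at -1.01 ± 0.58. That list had 4 lower without hepatic metastasis replicate 9, 3 without lymph node replicate 4 and 2 without hepatic metastasis replicates 5 or 6. DESeq2 called 2118 genes, 66.9% of them higher against 56.2%, and UMIs per spot as a covariate gave 46.2%. The hepatocyte score as a covariate gave 251, 52 of them shared. With it ALB was at 0.80 ± 0.88, which was set in advance, since ALB is part of that score. MS4A1 (-7.66 ± 3.30), CD79A (-7.02 ± 2.09) and CCR7 (-5.75 ± 2.36) had folds as large as without the covariate and wider errors, and were not called.

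Genes changed at both metastatic sites against primary tumours were counted. Both comparisons called 33 genes higher and 222 lower, against 25.8 and 19.3 for independent lists, and 6 went opposite ways. Those lower at both included COL11A1, COL12A1, INHBA, MMP2, APOD, SFRP2, the stromal gene LRRC15 and the islet genes GCG, INS and CHGA. Those higher at both included CD5L, TIMD4 and SPIC, which tissue macrophages of liver and spleen express, the sinusoid genes STAB2 and CLEC4M, and the lipid carriers CETP and FABP1. Over all genes the fold changes of the 2 comparisons correlated at r = 0.252, and at 0.409 on average in 20 simulated data sets of unchanged groups with shared controls, so this r alone cannot show a shared change. The covariance was 0.263 against 0.087 in the simulations. In the 2 splits of the primary tumours given next, which share no control, r was 0.071 and 0.083. These values were not tested. With the primary tumours split into 5 and 5, 7 genes were higher and 74 lower at both sites, and with the parts exchanged 7 and 84. DESeq2 gave 44 and 353. For independent lists the splits would give 5.52 and 6.23 in the first and 11.8 and 10.4 in the second, so the higher genes lay close to these numbers, above or below, and the lower genes far above.

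Moran's I described how far each gene's expression formed domains within a section. In primary tumours the highest mean values among genes with enough counts were those of FN1 (0.492 ± 0.137), COL1A1 (0.489 ± 0.110) and COL1A2 (0.478 ± 0.127). In hepatic metastases they were those of S100A6 (0.437 ± 0.220) and COL1A2 (0.382 ± 0.179), and in lymph nodes those of the immunoglobulin light chain IGKC (0.651 ± 0.124), S100A6 (0.614 ± 0.118) and the keratin KRT8 (0.565 ± 0.064). Of 2134 genes tested with limma, 72 had higher Moran's I in lymph nodes than in primary tumours and none lower. With the loess residual on gene count this balance turned, with 39 genes higher and 82 lower. The largest differences were in LGALS4, an intestinal galectin (0.518 ± 0.10 against 0.234 ± 0.130), SMCHD1 (0.296 ± 0.232 against 0.035 ± 0.032) and ANXA4 (0.375 ± 0.147 against 0.145 ± 0.112). LAPTM5 of blood cells was at 0.335 ± 0.143 against 0.114 ± 0.068. The calls of LGALS4 and ANXA4 were lost with 2 groups only (differences of 0.284 and 0.231), with UMIs per spot as a covariate (that of ANXA4 at 0.182) and without lymph node replicates 1 (0.270 and 0.199) or 3 (0.253 and 0.196) or primary tumour replicates 1 (0.267 and 0.218) or 7 (0.275 and 0.217). That of LGALS4 was also lost with the loess residual (0.136) and without lymph node replicate 5 (0.283) or primary tumour replicates 2 (0.269), 6 or 8 (0.278 each), and that of LAPTM5 with the residual (0.087) and without lymph node replicate 1 (0.170). In hepatic metastases 2 genes had lower values than in primary tumours, the YAP targets CCN2 (0.098 ± 0.094 against 0.364 ± 0.144) and CCN1 (0.080 ± 0.108 against 0.328 ± 0.171). Both calls were lost with the loess residual on gene count (-0.142 and -0.149), the number of spots as a covariate (-0.258 and -0.238), 2 groups only, a minimum of 20 counts, and without the other file layout (-0.252 and -0.221). They were also lost without hepatic metastasis replicates 1, 2, 4, 6, 7, 8, 9, 11 or 12 or primary tumour replicates 1, 3, 5, 7, 9 or 10, with differences there of -0.250 to -0.268 for CCN2 and -0.227 to -0.252 for CCN1. In primary tumours 8 had lower values than in normal pancreas, among them the chaperones HSPA1A (0.078 ± 0.059 against 0.544 ± 0.407) and DNAJB1 (0.062 ± 0.056 against 0.469 ± 0.380). Both were lost without normal pancreas replicates 1 (-0.347 and -0.303) or 2 (-0.351 and -0.292). Leaving out single specimens gave 16 to 398 genes for lymph nodes, 0 to 3 for hepatic metastases and 2 to 14 for normal pancreas. With log2 UMIs per spot as a covariate (12.57 ± 0.565 in lymph nodes against 11.62 ± 0.755, exact permutation adjusted p = 0.0666) 31 genes were called, and the median difference of the 72 was 0.071 against 0.079 without it.

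Medians of Moran's I over lists carry no count minimum, so a list nearly absent from a group lies near 0 there and its difference restates the level. This holds for hepatocyte genes, at 0.340 ± 0.236 in hepatic metastases and 0.000 ± 0.002 in primary tumours (permutation adjusted p = 0.00174), where their score was 1.22. It holds for islet genes, at -0.001 ± 0.000 in hepatic metastases against 0.062 ± 0.103 (permutation p = 2.0e-05, adjusted p = 0.00174), and in lymph nodes (scores of -0.548 and -0.605), and the low counts of the other lists were not ruled out as a cause. Schwann cell genes had 0.000 ± 0.001 against 0.033 ± 0.056 (adjusted p = 0.0145). Without primary tumour replicate 10 the primary tumour means fell to 0.019 for Schwann cell and 0.031 for islet genes, and both tests passed. In lymph nodes, B cell genes were at 0.149 ± 0.070 against 0.016 ± 0.036 (exact permutation adjusted p = 0.0232), T and NK cell genes at 0.045 ± 0.019 against 0.010 ± 0.010 (0.029) and MHC class II genes at 0.210 ± 0.102 against 0.059 ± 0.033 (0.0145). Ductal genes were at 0.382 ± 0.085 against 0.174 ± 0.101 (exact permutation adjusted p = 0.0406). Plasma cell and T cell checkpoint genes were also higher and islet genes lower (adjusted p = 0.0406 each), and interferon response genes higher (0.0435). Primary tumours exceeded normal pancreas in myofibroblastic (0.194 ± 0.111 against 0.021 ± 0.005), SPP1-type macrophage (0.069 ± 0.049 against 0.013 ± 0.005) and lymph node stroma genes (0.044 ± 0.059 against -0.001 ± 0.001; exact permutation adjusted p = 0.0435 each). With the loess residual on gene count, 5 of these 14 tests still passed, 3 of them those of hepatocyte and islet genes, and the others Schwann cell genes in hepatic metastases and T and NK cell genes in lymph nodes. Immediate early and heat shock genes, not called as deposited (-0.045, adjusted p = 0.101), passed with the residual, lower in hepatic metastases by 0.028 (adjusted p = 0.00696). Leaving out single specimens, 4 to 27 tests passed against 14. The hepatocyte, islet and Schwann cell tests in hepatic metastases and that of MHC class II genes in lymph nodes passed each time. The 27 came without hepatic metastasis replicate 5, with hepatic metastases lower in collagen and matrix (-0.119), myofibroblastic (-0.117), smooth muscle (-0.080), immediate early and heat shock (-0.056), hypoxia and glycolysis (-0.033) and endothelium genes (-0.018). The other gains were in comparisons without hepatic metastases, where p did not change and only its adjustment over all tests did. Smooth muscle genes also passed without hepatic metastasis replicate 10 (-0.082) or primary tumour replicates 6 or 8 (-0.085 each), and endothelium genes without hepatic metastasis replicates 10 or 11 (-0.019 each) or primary tumour replicates 1, 6 or 8 (-0.020 each). In lymph nodes, classical subtype (0.103) and pancreatic cancer epithelium genes (0.192) passed without primary tumour replicate 10, lymph node stroma without lymph node replicate 4 (0.187) or primary tumour replicate 3 (0.168), and proliferation genes without lymph node replicate 2 (0.038) or primary tumour replicate 5 (0.034). Against normal pancreas, acinar (-0.426), basal-like subtype (0.042), immediate early and heat shock (-0.214), macrophage (0.040) and proliferation genes (0.018) passed without primary tumour replicates 5, 6, 3, 8 and 1, in this order. The 3 tests of primary tumour against normal pancreas were lost without normal pancreas replicates 1, 2 or 3 or primary tumour replicates 2, 4, 7 or 9, and that of lymph node stroma fell from 0.045 to 0.028 without primary tumour replicate 3. The other 7 tests in lymph nodes were lost without lymph node replicates 1, 3 or 5, and T and NK cell genes also without lymph node replicate 4 (0.033). Checkpoint, plasma cell, ductal and interferon response genes were lost without lymph node replicate 4, ductal and islet genes without lymph node replicate 2, and these 5 lists without primary tumour replicates 2, 4 or 7, all but islet genes without replicate 9, and interferon response genes without replicate 8. Adjusted p in these ran from 0.0511 to 0.123, with group sizes that also raise the smallest p an exact permutation can give.

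**Figure D3:**
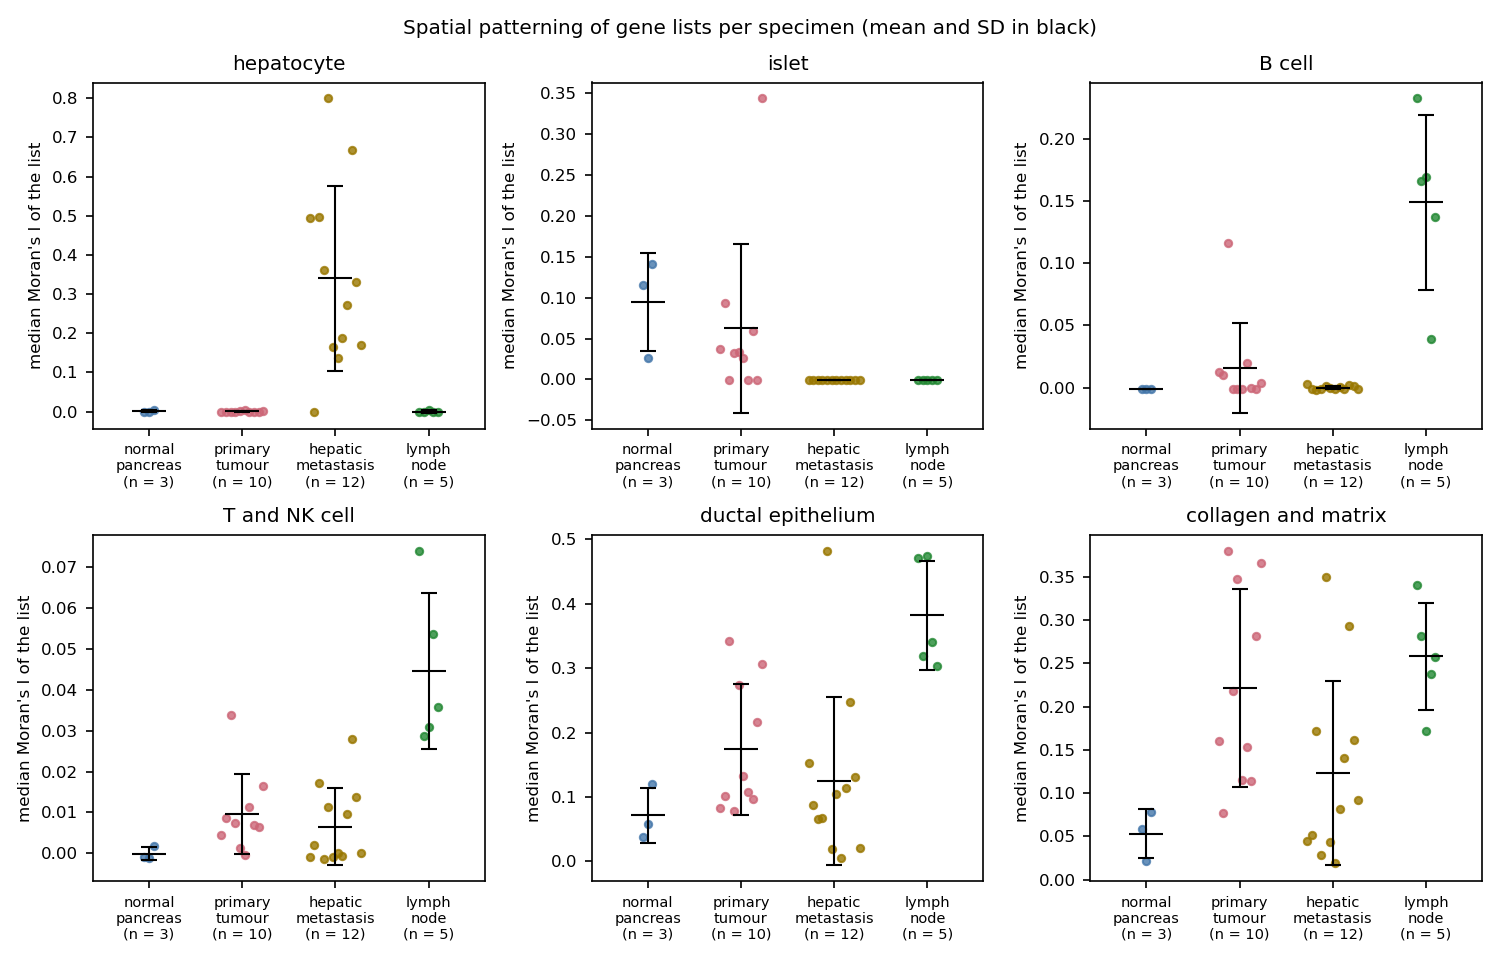
Median Moran's I of the members of 6 gene lists (vertical axes) in each specimen (points) by group (horizontal axes), with the group mean and SD in black. Hepatocyte genes averaged 0.340 in hepatic metastases, and B cell genes 0.149 and ductal genes 0.382 in lymph nodes.

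Scores of the classical and basal-like subtype lists were compared across specimens, a family of 2 correlations over 23 and 20 genes. In the 10 primary tumours Pearson's r was 0.150 (permutation p = 0.694, adjusted p = 0.694) and Spearman's rho 0.018 (p = 0.978), and r was -0.234 without the 2 specimens farthest from the median classical score. In the 12 hepatic metastases r was 0.589 (permutation p = 0.0434, adjusted p = 0.0869) and rho 0.545 (p = 0.0702, adjusted p = 0.14), and r was 0.524 without the 2 farthest. Neither passed after adjustment. Relative to KRT8, KRT18 and EPCAM, r was -0.355 in primary tumours (rho -0.515, r -0.532 without the 2 farthest) and 0.253 in hepatic metastases (rho -0.035, r -0.345 without the 2 farthest), so the sign in hepatic metastases rested on few specimens.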

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

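The tests in this part, including the splits of the specimens, were chosen after the results were seen, although UMIs per spot as a covariate of gene levels and the loess residual were among the settings chosen before. The rules for the dilution test and the depth test of Moran's I were rewritten after their first values were seen. A specimen was singled out where its gap to the nearest other of its group, over the group's range, passed Dixon's critical value. This covered primary tumours and lymph nodes, while normal pancreas (3) and hepatic metastases (12) were not examined. For independent, normally distributed values chance gives about 1 in 20, and 20 of 120 were found. The lists share specimens and some members, and many medians of Moran's I lie near 0, so the 2 shares cannot be compared. Primary tumour replicate 3 had the highest B cell score (4.229, the next 1.31) and the highest median Moran's I of B cell (0.116), lymph node stroma (0.197) and T and NK cell genes (0.034), a set of genes of lymphoid tissue. Primary tumour replicate 5 had the lowest macrophage score (4.882, the next 5.77) and the highest Moran's I of acinar genes (0.60, the next 0.234). Primary tumour replicate 10, whose file had another layout, had the highest Moran's I of islet (0.344), classical (0.207), basal-like (0.149) and neutrophil genes (0.031). Lymph node replicate 3 had the highest acinar score (5.801, the next 0.785) and hepatocyte score (1.574), with Moran's I of 0.110 and 0.005 for these lists. Lymph node replicate 4 had the lowest B cell score (1.078, the next 5.78), and the highest Moran's I of macrophage (0.139) and neutrophil genes (0.032). Lymph node replicate 1 had the highest Moran's I of mesenchymal transition genes (0.152), and lymph node replicate 5 of Schwann cell (0.022) and adipocyte genes (0.069).

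Collagen and matrix genes were lower in hepatic metastases than in primary tumours, with a median of -1.70. With UMIs per spot as a covariate the median was -1.63, which argues against depth as the whole cause. Dilution by liver tissue stayed open. It would lower collagen and pancreatic cancer epithelium genes alike, and the difference of the 2 scores was 1.82 ± 2.36 (SD, n = 12) against 2.64 ± 1.61 (n = 10), a change of -0.81 (SE 0.85, permutation p = 0.368) that decides neither way. A smaller stroma at this site also stayed open, untested.

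Moran's I was higher in lymph nodes for 72 genes, and deeper libraries could raise it. The median difference of these genes was 0.071 with UMIs per spot as a covariate against 0.079 without, but 17 of the 72 passed with the loess residual on gene count. That setting called 39 genes higher and 82 lower, so depth and site cannot be told apart. Chance could not be excluded, since 5 of 100 splits of the specimens gave as many genes and the highest other gave 633, for a reason that was not examined. Nor could it for the 8 genes of primary tumour against normal pancreas, where 9 splits of 100 gave as many and the highest other gave 29. For the 2 genes of hepatic metastasis against primary tumour, 2 of 100 splits gave as many, under the 0.05 level for the count if specimens are independent, and the highest other gave 4. Both calls were lost in 5 other settings and without 15 of the 22 specimens, where the differences stayed at -0.227 to -0.268, against -0.142 and -0.149 with the loess residual, so the 2 genes are not established.

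All measured collagen, macrophage and MHC class II genes, and 15 of 17 cancer epithelium genes, were called higher in primary tumours than in normal pancreas. Loss of acinar tissue alone would raise every other cell type alike. The collagen score minus the endothelium score, a comparator picked with its median already seen, was 5.28 ± 0.75 (SD, n = 10) in tumours and 0.31 ± 0.66 (n = 3) in normal pancreas, a difference of 4.98 (SE 0.45, exact permutation p = 0.0035), which argues against it as the whole cause. The tumour itself and its stroma stayed open as the source, untested, as did the median of 1.57 over all genes without TMM, against -0.019 with it.

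In each comparison the real split alone of 100 gave as many changed genes, the smallest share this test can give. That argues against chance for the counts if specimens are independent, which the labels cannot show. Primary tumour against normal pancreas had 4517 against a highest other of 705, and hepatic metastasis against primary tumour 1659 against 751. Lymph node against primary tumour had 909 against 551, and hepatic metastasis against lymph node 1668 against 1002. Without lymph node replicate 2 or 5, lymph node against primary tumour gave 269 or 476 genes, under 551, and these sets were not split anew.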

How the results depend on the processing

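The settings without 3 specimens of another file layout, of atypical tissue content or under 1000 UMIs per spot, UMIs per spot as a covariate of Moran's I, and left-out specimens for list medians of Moran's I, were chosen after the data were seen, and the others before. Of 2216 values of named genes under other settings, 2057 kept their direction and side of the threshold, 118 lost the call, 20 gained it and 21 reversed, and of 3034 that left out a specimen 2976, 44, 12 and 2 did. Changed genes in primary tumour against normal pancreas were 10902 without TMM against 4517. In hepatic metastasis against primary tumour they were 3041 with no fold minimum and 170 with the hepatocyte score as a covariate against 1659, in lymph node against primary tumour 1403 with DESeq2 and 181 with the B cell score against 909, and in hepatic metastasis against lymph node 251 with the hepatocyte score against 1668. These 2 covariates nearly follow the groups, and reversed, in hepatic metastasis against primary tumour, CXCL2 (-0.544), C3 (-1.400), FCN2 (-1.167), FCN3 (-1.346) and APOC1 (-2.896), in hepatic metastasis against lymph node C3 (-0.050), FCN2 (-1.330), CD14 (-0.641) and APOE (-0.555), and in lymph node against primary tumour BLK (-1.377), FCRL1 (-0.762), MS4A1 (-0.441), NIBAN3 (-0.079), CD79A (-0.339), CCL21 (-0.889), AC119396.1 (-0.797), CCR7 (-1.323), CLEC4M (-0.810), CD3E (-0.492) and POU2AF1 (-0.663). Of these, BLK, FCRL1, MS4A1 and CD79A are part of the B cell score itself. LIPF reversed in hepatic metastases with DESeq2 (1.078) and without primary tumour replicate 7 (2.868), with -8.472 the lowest leaving out single specimens, and in lymph nodes without primary tumour replicate 7 (0.141), with -9.693 the lowest. The correlation of subtype scores in primary tumours reversed relative to epithelial genes (-0.355). Leaving out single specimens gave 3167 to 4524, 1420 to 1876, 269 to 1070 and 1149 to 1868 changed genes in the 4 comparisons, in the order above. Genes with different Moran's I in primary tumour against normal pancreas (8) were 22 with the loess residual, 3 at 500 counts or more, 40 at 20 or more, 5 with spots as a covariate, 15 with 2 groups only, 8 with UMIs per spot (3 higher, 5 lower) and 2 to 14 leaving out single specimens. In hepatic metastasis against primary tumour (2) they were 0 with the residual, at 500 counts, with spots, with 2 groups only and without the other layout, 13 with UMIs per spot (11 higher, 2 lower, these the same 2), 3 others at 20 counts (all higher) and 0 to 3 leaving out single specimens. In lymph node against primary tumour (72) they were 121 with the residual (39 higher, 82 lower), 0 at 500 counts, 578 at 20, 222 with 2 groups only, 31 with UMIs per spot, 158 without the other layout and 16 to 398 leaving out single specimens. Lists with a different median Moran's I were 6 with the residual and 4 to 27 leaving out single specimens, against 14. Genes changed at both sites were 397 with DESeq2 and 81 and 91 with the primary tumours split, against 255. Lists passing camera were 0, 1, 1 and 1 with an estimated correlation against 17, 10, 19 and 11, and with fry 8 in lymph node against primary tumour and 6 in hepatic metastasis against lymph node. Apart from the minimum of 500 counts, which tests 111 genes against 2134, and left-out specimens, the cause was not tested. No paired analysis was possible because the labels do not link specimens to patients. Depth limits Moran's I to the 2134 genes with enough counts, against 16810 tested for level.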

Other observations

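The test of stomach gland genes below was chosen after LIPF was seen, and its gene list and prediction were written before those genes were examined. In primary tumour against normal pancreas the remaining lists gave 4 of 12 B cell genes higher (4 adjusted over the list alone, camera adjusted p = 0.0431, adjusted p = 0.622 with an estimated correlation) and 6 of 8 lymph node stroma genes (7 over the list alone, 0.00298, adjusted p = 0.284 with an estimated correlation). Hypoxia and glycolysis genes had 6 of 13 higher and 2 lower (camera adjusted p = 0.0618), smooth muscle 4 of 6 higher (0.163) and endothelium 3 of 13 higher (0.225). Adipocyte genes had 1 of 8 lower (0.518). The B cell list had 1 called without normal pancreas replicate 1, 2 or 3, 2 without primary tumour replicate 3, 1 with limma voom or UMIs per spot as a covariate and 9 with DESeq2. The lymph node stroma list had 3 and 2 without normal pancreas replicates 1 and 2, and 3 with limma voom or UMIs per spot, smooth muscle 2 without any of these 3 specimens, and endothelium 1 without normal pancreas replicates 1 or 3. Lists given here with 3 or fewer called genes in any comparison gained or lost calls in many settings that left out 1 specimen, so their counts carry little weight. In 4 lists the median and mean differed in sign and camera pointed down without passing, namely ductal (0.63 and -0.03), liver sinusoid (0.14 and -0.16, 1 of 8 lower), hepatocyte (0.09 and -0.29, 1 of 21 higher and 3 lower) and Schwann cell genes (-0.32 and 0.03, 1 of 8 each way). ALB was lower in primary tumours at -6.95 ± 1.23.

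In hepatic metastasis against primary tumour, mesenchymal transition genes had 2 of 12 lower (camera adjusted p = 0.0204, adjusted p = 0.64 with an estimated correlation), adipocyte genes 3 of 8 higher (0.109), classical genes 2 of 23 lower (0.146) and endothelium genes 1 of 13 higher (0.47). Checkpoint (0.34), B cell (0.983) and lymph node stroma genes (0.959) had 1 lower each, and basal-like (0.34), ductal (0.57) and heat shock genes (0.127) 0 called by edgeR. Signs differed for neutrophil (-0.04 and 0.04) and MHC class II genes (-0.06 and 0.02), both down by camera, and the B cell list had a median of -0.28 with camera up. In lymph node against primary tumour camera passed for proliferation genes upwards (0.0134, adjusted p = 0.587 with an estimated correlation). It passed downwards for macrophage (0.0197, adjusted p = 0.587 with an estimated correlation), hypoxia (0.04, 0.429), Schwann cell (0.04, 0.498), neutrophil (0.0445, 0.498), hepatocyte (0.045, 0.721) and smooth muscle genes (0.045, 0.553), the second value of each pair with an estimated correlation. Of these, edgeR called 2 of 8 Schwann cell genes and 1 of 21 hepatocyte genes lower. Camera did not pass for acinar (0.0967), SPP1-type macrophage (0.195), adipocyte (0.226), heat shock (0.247), inflammatory fibroblast (0.29), interferon (0.296), basal-like (0.332), endothelium (0.679, median -0.02 and mean 0.04), pancreatic cancer epithelium (0.753, median 0.07 with camera down) and ductal genes (0.974).

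In hepatic metastasis against lymph node MHC class II genes had 1 of 10 lower (camera adjusted p = 0.00143, adjusted p = 0.566 with an estimated correlation). Neutrophil (0.19) and mesenchymal transition genes (0.219) had 1 higher each, smooth muscle (0.331), endothelium (0.685) and ductal genes (0.61) 1 lower each, Schwann cell genes (0.558) 1 each way, adipocyte genes (0.595) 2 higher and hypoxia genes (0.479) 2 lower. Myofibroblastic (0.331), acinar (0.61), heat shock (0.627), interferon (0.702), basal-like (0.813), islet (0.877) and collagen genes (0.952) had 0 called by edgeR. Camera pointed down against a positive median for basal-like (0.21), heat shock (0.04) and collagen genes (0.006).

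LIPF, gastric lipase, was at 1845 CPM in primary tumour replicate 7 and at 0.562 CPM or less in the other 9 primary tumours. A hypothesis was that this section may hold stomach glands. Of 12 other stomach gland genes, 8 were highest in that specimen, among them PGC (732 CPM) and PGA5 (620.0 CPM), while TFF2 (1.09 against up to 588 CPM), MUC6, GKN2 and CCKBR were not. The count of 8 lay between the bounds set for and against the hypothesis, 3 in 4 and 1 in 2. By this rule the hypothesis stayed undecided, and another source of these genes was not examined.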
